A study of Mus musculus with 2 samples.

How the data were processed

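Gene expression was measured on 2 one-colour Affymetrix arrays, 1 for each of 2 groups, in primary mouse hepatocytes. Per the labels' protocols, biotin-labelled cRNA for each array was made from 5 µg of total RNA pooled from 3 samples. The deposited values are GCRMA intensities on a linear scale, and GCRMA 2.2.0 is named in the submitters' processing notes. GCRMA corrects probe signals for background with a model of probe sequence, normalizes the arrays to each other and summarises the probes of a set into 1 value. The scale was read from the deposited intensities, which ran from 1.13 to 28482 with none at or below 0, so they were not log values. Because GCRMA brings arrays to a common distribution, a change in total RNA per cell cannot be seen in these intensities.

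The deposited table held 16395 probe sets. Of these, 64 were Affymetrix controls and 15644 had 1 gene symbol in the platform annotation, with none carrying several. The other 687 probe sets were unnamed here and stayed out of the gene counts. The table held no more than 1 probe set for any named gene, each probe set being numbered by its Entrez gene. Of the Entrez numbers, 15617 were found in the RefSeq gene table of assembly GRCm38.p6, in every case with the same symbol. The build and probe set definition behind the deposited intensities are not given in the sources used here, so no coordinates are given.

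From the deposited intensities, log2 values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the difference was taken as PCN minus DMSO. A floor of 5 on the log2 scale (an intensity of 32) was set. Genes under the floor in both arrays counted as not measured. A value under the floor in 1 array was raised to it, so that the fold is a lower bound and is written as "at least". The deposited table has no detection calls, and the floor is a choice, not a measured background. A difference of 1 on the log2 scale (2-fold) was the size threshold for counts. Each group had 1 array, so no test, standard error or p-value was computed, and "higher" and "lower" describe these 2 arrays only. Depth has no meaning for array intensities, and the number of arrays limits the precision.

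The bacterial and phage control probe sets served as a measure of array-to-array spread. Over the 40 of them that passed the floor, the log2 difference had a mean of -0.04 and an SD of 0.11, with a range from -0.33 to 0.16. These controls are added from outside, and their spread does not include differences between cultures.

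Before the data were examined, 22 gene lists, the floor, the threshold, the alternatives and the rule for named genes were fixed. For each list, the median log2 difference of its measured members was compared with the medians of 10000 random lists of the same size, matched on mean expression in 20 bins of equal size. The resulting percentile describes these 2 arrays and is not a test of the treatment. The genes of a list are not independent, so several lists outside the central 95% of random lists can share 1 source. By size alone, 1.1 of 22 unrelated lists would fall outside it. The named genes are the 12 with the largest difference each way among genes at or above the floor in both arrays, and the 3 largest bounds each way among the others. Uncharacterised gene models, recognised by their symbols, were left out of both. The 4 members of each list with the largest difference and 14 genes fixed by name were added. Genes named outside this rule are marked as chosen after their values were seen.

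The procedure was tested on simulated arrays with 200 genes changed 2.83-fold among measured genes well above the floor. It recovered 100.0% of them and called no other gene. The simulated noise was smaller than the SD of 0.23 of the real log2 differences over genes. This outcome was therefore near certain, and changes of dim genes were not tested. A list of 20 genes shifted by 0.3 on the log2 scale lay at percentile 100.0, and 5 of 100 random lists fell outside the central 95%. Both of these outcomes were also near certain, since the noise was small and independent between genes and random lists were compared with random lists. They do not show how percentiles behave for real lists, whose genes are not independent. The alternatives were a floor of 4 or 6, values under the floor as deposited, quantile normalization, centring on the median difference, removal of a loess trend (statsmodels 0.14.6, fraction 0.3), other size thresholds and lists without a floor. Dates or batches of the arrays were not used here, and with 1 array per group a batch and the treatment cannot be told apart.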

Results

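Pregnenolone 16α-carbonitrile (PCN) is a synthetic steroid that activates the pregnane X receptor (PXR) in rodents, a nuclear receptor that controls genes of drug metabolism. The study asked how PCN alters gene expression in primary hepatocytes, liver parenchymal cells isolated from the organ and kept in culture. The cells came from a male C57BL/6 mouse aged 9 weeks and were cultured for 24 h before treatment. They then received 10 µmol/l PCN or the solvent dimethyl sulfoxide (DMSO) for 12 h. RNA from 3 samples was pooled in each group and hybridised to 1 array, so there were 2 arrays, 1 per group, and no replicates. Every value below is a single array's value, and no difference could be set against a spread between cultures. The median intensity over all probe sets was 14.4 in the DMSO array and 14.1 in the PCN array. Of the named genes, 6345 (40.6%) reached the floor in the DMSO array and 6333 (40.5%) in the PCN array. In all, 6449 genes were measured, 6229 of them in both arrays.

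The PCN array differed from the DMSO array by 2-fold or more in 21 of the 6449 measured genes. PCN was higher in 6 of them and lower in 15. Over all measured genes, whatever the size of the difference, PCN was higher in 3714 and lower in 2735, the split against which the counts of the lists stand. Of the 22 lists, 10 lay below and 2 above the central 95% of random lists. The largest difference was that of Cyp3a25, a cytochrome P450 of the CYP3A family, which was 7.82-fold higher with PCN. Thbs1, which encodes the matricellular glycoprotein thrombospondin 1, was 4.88-fold higher. The largest difference in the other direction was that of Cyp26a1, the cytochrome P450 that clears retinoic acid, which was at least 6.19-fold lower. Slc2a2, which encodes the glucose transporter GLUT2, was 2.71-fold lower. Across genes, the 2 arrays correlated with a Pearson r of 0.994 over the measured genes, which are not independent replicates. The middle of the distribution of log2 differences ran from -0.09 at the 25th percentile to 0.14 at the 75th, around a median of 0.03.

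**Figure D1:**
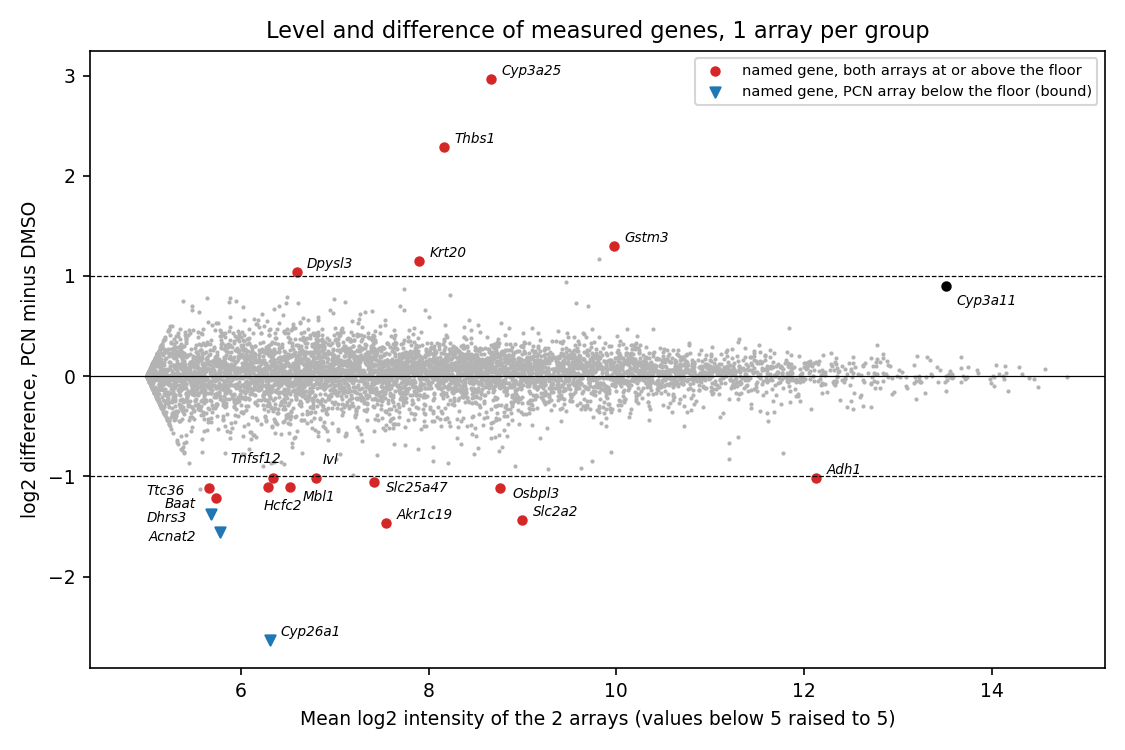
Log2 difference (PCN minus DMSO, vertical axis) against mean log2 intensity of the 2 arrays (horizontal axis) for the 6449 measured genes, 1 point per gene, with dashed lines at a 2-fold difference, red points and blue triangles for named genes past it and a black point for Cyp3a11. Cyp3a25 at 2.97 and Thbs1 at 2.29 stand highest, and Cyp26a1, a bound because its PCN value was under the floor, stands lowest at -2.63.

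Besides Cyp3a25 and Thbs1, the named genes that were 2-fold or more higher were Gstm3, Krt20 and Dpysl3. Gstm3, a glutathione S-transferase, went from an intensity of 641 to 1580, a 2.47-fold difference. Krt20, an intermediate filament keratin, was 2.21-fold higher, and Dpysl3, a cytoskeleton-associated protein of the dihydropyrimidinase-like family, was 2.05-fold higher. The remaining gene of the 6 has a symbol of the kind given to uncharacterised gene models. Under the 2-fold threshold, the next were Hmga2, an architectural chromatin protein, at 1.92-fold, and Cyp3a11, the main drug-metabolising CYP3A enzyme of mouse liver, at 1.87-fold. Gadd45a, a growth arrest and DNA damage response gene, was 1.83-fold higher. Odc1, the first enzyme of polyamine synthesis, was 1.75-fold higher, and the cytokine gene Il33 was 1.73-fold higher. Zfp955b, a zinc finger gene, and Rin3, a guanine nucleotide exchange factor for Rab proteins, stood at 1.72-fold each. Among genes under the floor with DMSO, no lower bound reached 2-fold, although with values as deposited the number of genes higher by 2-fold was 8 in place of 6. The highest bounds were those of Pcf11, an mRNA 3' end processing factor, at least 1.42-fold, Abcb1a, a drug efflux pump, at least 1.38-fold, and Sphk1, a sphingosine kinase, at least 1.38-fold.

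Of the 15 genes that were 2-fold or more lower with PCN, 11 were at or above the floor in both arrays and 4 were under it in the PCN array. Akr1c19, an aldo-keto reductase, was 2.77-fold lower, and Baat, which conjugates bile acids to amino acids, was 2.32-fold lower. Adh1, an alcohol dehydrogenase that also oxidises retinol, was 2.03-fold lower at a high level, from an intensity of 6383 to 3150. Osbpl3, an oxysterol-binding protein family member, was 2.16-fold lower, and Slc25a47, a mitochondrial carrier of the liver, was 2.07-fold lower. Mbl1, a mannose-binding lectin, was 2.15-fold lower. Hcfc2, Ttc36, Ivl and Tnfsf12 were lower by 2.15-fold, 2.17-fold, 2.03-fold and 2.02-fold. Scly, the selenocysteine lyase gene, lay just under the threshold at 1.98-fold. Of the genes under the floor with PCN, Acnat2, an acyl-CoA:amino acid N-acyltransferase, was at least 2.94-fold lower. Dhrs3, a retinaldehyde reductase, was at least 2.60-fold lower. The remaining one, Pdk2, a pyruvate dehydrogenase kinase, was named after its value was seen and was at least 2.18-fold lower.

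Genes known as targets of PXR were higher with PCN as a group. Of 26 listed genes, 19 had a named probe set and 16 were measured. Of these 16, 13 were higher with PCN and 3 lower, and 4 were higher by 1.5-fold or more, with none lower by that much. The median log2 difference was 0.27, above all 10000 random lists. The 4 were Gstm3 and Cyp3a11, given above, Ces2a, a carboxylesterase, at 1.65-fold, and Cyp2c29, a CYP2C enzyme, at 1.63-fold. The 3 lower members, named after their values were seen, were Aldh1a7 at -0.36, Abcc3 at -0.07 and Aldh1a1 at -0.007 on the log2 scale. Alas1, the first enzyme of heme synthesis, was 1.23-fold higher, from 884 to 1088. Cyp2b10, the usual marker of the receptor CAR, was close to the floor, with intensities of 25.9 with DMSO and 35.4 with PCN. Abcb1a went from 17.5 to 44.2, the first of these under the floor. Nr1i2, the gene of PXR itself, had intensities of 71.9 and 70.1. The transporter gene Slco1a4 and Nr1i3, the gene of CAR, were under the floor in both arrays, and Por was not analysed here. Members of the CYP3A, CYP2C and glutathione transferase families have closely related sequences, and these intensities do not show how far a probe set also reads a relative. Cyp3a11 ranked 65 of 6449 measured genes by intensity with DMSO, a level at which array signal can be compressed.

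**Figure D2:**
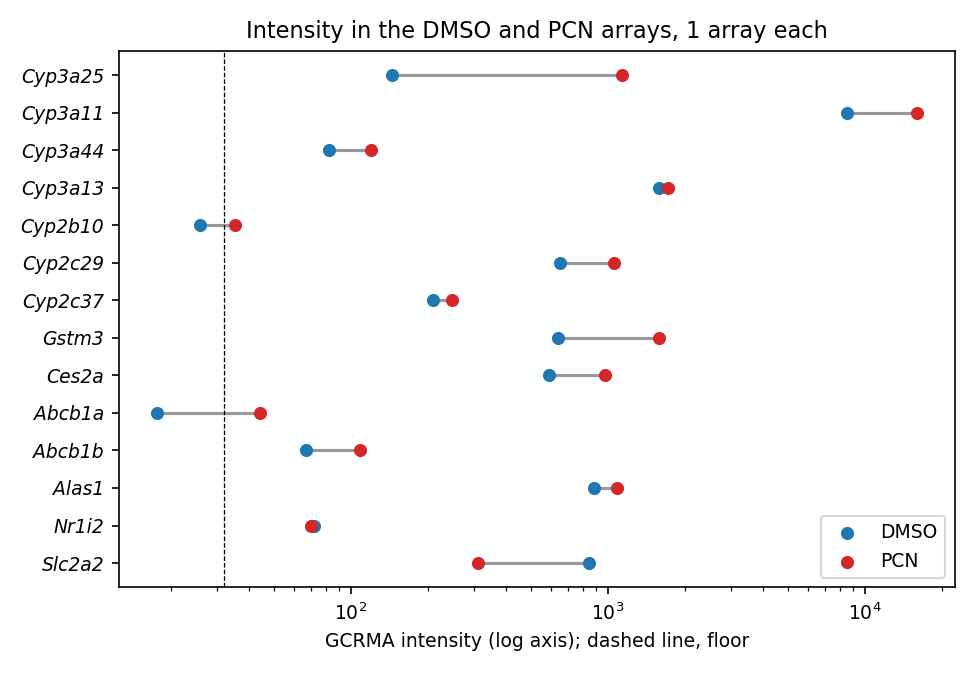
GCRMA intensity on a log axis in the DMSO array and the PCN array for 14 genes, with a line joining the 2 values of a gene and a dashed line at the floor of 32. Cyp3a25 moved from 145 to 1134 and Cyp3a11 from 8519 to 15919, while Slc2a2 lies lower with PCN, at 311 against 842.

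The 12 measured P450 genes of families 1 and 2 outside the PXR list had a median log2 difference of 0.05, at percentile 65.9 of random lists, with 7 higher and 5 lower; the median was -0.11 when all members were taken without a floor. Cyp2a12 was 1.69-fold lower, Cyp2d22 1.34-fold lower and Cyp2d9 1.25-fold lower, and Cyp2e1 was 1.24-fold higher. Conjugation enzymes outside the PXR list were lower in 20 of 27 measured genes, with a median of -0.18, below all 10000 random lists. None of them reached 1.5-fold. Their largest differences were those of Gstm6 at 1.35-fold, Gstz1 at 1.26-fold, Gsta3 at 1.26-fold and the sulfotransferase Sult1a1 at 1.26-fold, all lower. Of 8 measured transporters of drugs and bile acids, 2 were higher and 6 lower, with a median of -0.03 at percentile 14.6. Abcb1b, a second multidrug efflux pump, was 1.62-fold higher, and Abcc4 was 1.17-fold higher. Slc22a18 was 1.43-fold lower, and the phospholipid transporter Abcb4 was 1.35-fold lower.

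Genes of glucose handling were lower with PCN in 12 of 16 measured members, with a median log2 difference of -0.27, below all 10000 random lists. Lower by 1.5-fold or more were 2 of them, Slc2a2 and Slc37a4, the glucose-6-phosphate transporter gene, the latter at 1.63-fold. Ppp1r3b, a glycogen-targeting phosphatase subunit, was 1.49-fold lower, and Fbp1, fructose-1,6-bisphosphatase, was 1.41-fold lower. The gluconeogenic genes Pck1 and G6pc were under the floor in both arrays, so no difference could be given for them. Bile acid genes were lower in all 10 measured members, with a median of -0.30, again below all 10000 random lists. After Baat, the largest differences were those of Cyp39a1, an oxysterol hydroxylase, at 1.42-fold, Nr1h4, the gene of the bile acid receptor FXR, at 1.27-fold, and Hsd3b7 at 1.25-fold. Only Baat of these 10 passed 1.5-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was under the floor in both arrays.

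Genes of fatty acid oxidation and ketogenesis were lower with PCN in 18 of 21 measured members, with a median of -0.21, below all 10000 random lists. Bdh1, a ketone body dehydrogenase, was 1.64-fold lower and the only member past 1.5-fold. Ppara, the gene of the lipid-sensing receptor PPARα, was 1.42-fold lower, Cyp4a12a 1.34-fold and Acaa2, a mitochondrial thiolase, 1.22-fold. Lipid synthesis and storage genes showed a smaller median of -0.04, at percentile 2.15, with 11 higher and 19 lower, and this percentile reached 4.01 under other settings. Gpam, the first enzyme of glycerolipid synthesis, differed by -0.58 on the log2 scale, just under 1.5-fold, and the fatty acid transporter Cd36 was 1.44-fold lower. Fabp1 was 1.37-fold higher and Elovl6 1.30-fold higher. Of 17 measured cholesterol genes, 14 were lower, with a median of -0.13 at percentile 0.16. Their largest differences were those of Dhcr7 at 1.39-fold, Lss at 1.32-fold, Pmvk at 1.32-fold and Nsdhl at 1.25-fold, all lower, and none reached 1.5-fold.

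**Figure D3:**
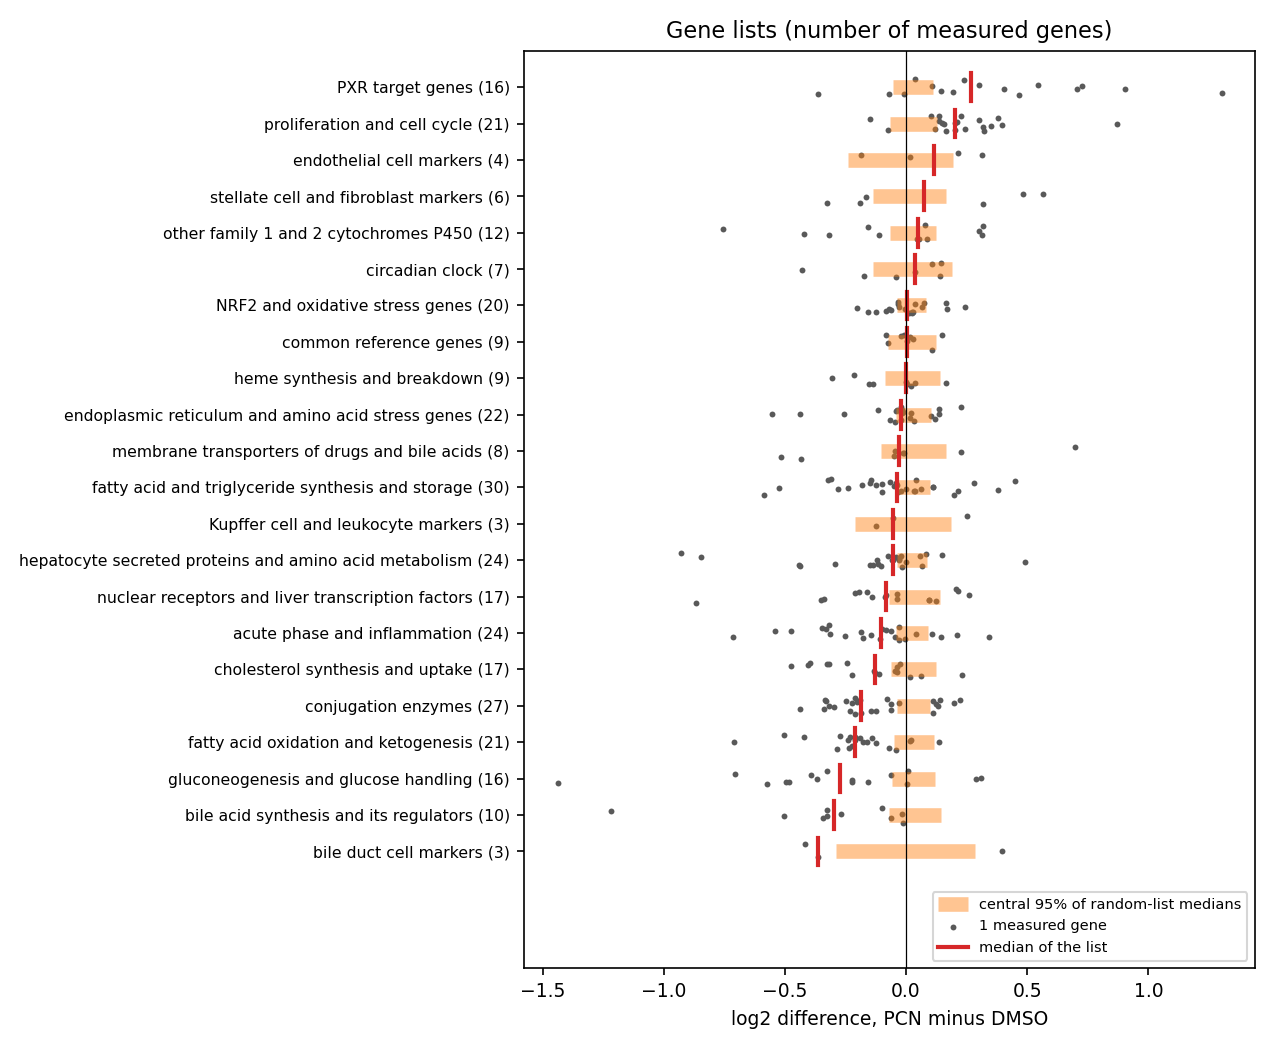
Log2 difference (PCN minus DMSO) of each measured gene in the 22 lists fixed in advance, with the list's median and the central 95% of medians of 10000 random lists matched on expression. PXR target genes and cell cycle genes lie highest of the lists outside the random range, at 0.27 and 0.20, and the bile acid, glucose handling and fatty acid oxidation lists lie at -0.30, -0.27 and -0.21.

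Cell cycle genes were higher with PCN in 19 of 21 measured members, with a median log2 difference of 0.20, above all 10000 random lists. Gadd45a was the only one past 1.5-fold. The lower members, named after their values were seen, were Plk1 at -0.15 and Ccna2 at -0.07. The list also holds growth arrest genes such as Gadd45a, so its median is not a measure of proliferation. The higher members were not limited to such genes. The replication genes Mcm2, Mcm3, Mcm4, Mcm5 and Mcm6, also named after their values were seen, were higher, from 0.12 for Mcm3 to 0.32 for Mcm4. Myc, a growth-related transcription factor, was 1.32-fold higher, Gadd45b 1.30-fold and Birc5, an inhibitor of apoptosis expressed in mitosis, 1.28-fold.

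Among 17 measured nuclear receptors and liver transcription factors, 6 were higher and 11 lower, with a median of -0.08 at percentile 1.69, which reached 5.26 under other settings. Cebpa, a transcription factor of differentiated hepatocytes, was 1.82-fold lower, Nr5a2 1.28-fold lower and Foxa3 1.26-fold lower, and Rxrb was 1.20-fold higher. Secreted proteins and amino acid enzymes of hepatocytes were lower in 19 of 24, with a median of -0.06 at percentile 0.23. Tdo2, which degrades tryptophan, was 1.90-fold lower, Arg1, the arginase of the urea cycle, 1.80-fold lower and Uox, urate oxidase, 1.36-fold lower. Hpd was 1.41-fold higher. Acute phase and inflammation genes were lower in 19 of 24, with a median of -0.10 at percentile 0.04. Steap4, a metalloreductase, was 1.64-fold lower, Saa4 1.45-fold, Lbp 1.39-fold and Apcs 1.27-fold. Other members of this list are named after their values were seen. Saa1 at -0.04, Saa3 at -0.004 and Lcn2 at -0.03 on the log2 scale barely differed. The 5 higher members included Nfkbia at 0.34, Cxcl2 at 0.21 and Socs3 at 0.15.

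The remaining lists lay within the central 95% of random lists, except bile duct markers. Heme genes outside the PXR list had 4 higher and 5 lower of 9, with Uros 1.24-fold and Ppox 1.16-fold lower. NRF2 and oxidative stress genes were evenly divided, 10 higher and 10 lower, with Osgin1 1.18-fold higher and Nqo1 1.15-fold lower. Of 22 endoplasmic reticulum and amino acid stress genes, 8 were higher and 14 lower, with Chac1 1.47-fold and Atf3 1.36-fold lower. Of 7 measured clock genes, 4 were higher and 3 lower, and Arntl was 1.35-fold lower. The 9 measured reference genes had a median of 0.00, with Actb at 16471 and 16524 and Tubb5 1.11-fold higher. The 3 control probe sets for 18S ribosomal RNA, a sign of the RNA preparation, differed by -0.42, -0.67 and -0.34, at intensities near or under the floor, with the largest at 69.6 with DMSO.

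Markers of other liver cell types were mostly under the floor. Of 15 stellate cell and fibroblast markers, 6 were measured, 3 higher and 3 lower, including Timp1 at 1.48-fold and Vim at 1.40-fold higher. Both of these genes are also expressed by cultured hepatocytes. Of 16 Kupffer cell and leukocyte markers, 3 were measured, 1 higher and 2 lower, with Cd68 1.04-fold lower. Of 13 endothelial markers, 4 were measured, 3 higher and 1 lower, with Lyve1 at least 1.24-fold higher. Of 10 bile duct markers, 3 were measured. Sox9 was 1.34-fold and Cd24a 1.29-fold lower, and Krt19 was 1.32-fold higher, with a median of -0.36 at percentile 1.11 that turned to 0.16 when all members were taken without a floor. With so few measured members, these lists give little information on the cell makeup of the cultures.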

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

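Every alternative was planned except the one with unnamed probe sets included, chosen after seeing the data. Of the 21 genes at least 2-fold apart, all 21 stayed so with a floor of 4, with low values as deposited, with quantile normalization and with median centring, and 20 with the loess trend removed. The count itself was 25 (8 higher, 17 lower) with a floor of 4 and with low values as deposited, 22 with quantile normalization or median centring and 21 with the loess trend removed. With a floor of 6, 14 stayed, 8 of them lower, which put the higher share at 42.9% against 28.6%, since a higher floor removes dim genes and shrinks bounds. At 1.5-fold there were 125 genes, 41 higher and 84 lower, and at 3-fold 3 genes, 2 higher and 1 lower. With unnamed probe sets included there were 22. None of the scalings moved the median of all genes by over 0.1. GCRMA had already brought the arrays to a common distribution, so these scalings could change little. Of 153 list medians under these settings, 147 stayed within the spike-in SD of the reported value and 6 moved by more. In all, 14 medians of 7 lists changed sign. Of these lists, only bile duct markers lay outside the random range; the heme, NRF2 and reference gene medians lay near 0, and NRF2 and reference genes also changed sign under scalings, to -0.03 with median centring. Without a floor, which adds members too dim to measure, the median was 0.40 for PXR target genes. Changed in sign in this setting were the other P450 genes at -0.11, stellate cell markers at -0.13, Kupffer cell markers at 0.062 and bile duct markers at 0.16, besides heme and reference genes near 0. With a floor of 6, stellate cell markers stood at 0.32 and no endothelial marker was measured. Under the settings with a floor, the lipid synthesis list ranged from percentile 0.45 to 4.01 and the transcription factor list from 1.5 to 5.26, so these lists did not stay outside the random range throughout. Of 19 named genes at least 2-fold apart, 12 stayed so under every setting that measured them, and no named gene at least 2-fold apart changed sign. Averaging probe sets and leaving out less specific ones could change nothing, since no named gene had more than 1 probe set and none carried such a suffix. No replicate could be left out with 1 array per group. No paired analysis was possible because each group had 1 array. Signal near background limits dim genes such as Cyp2b10, Pck1 and Cyp7a1.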

Other observations

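All tests in this part, and the cytoskeleton, wound response, growth response and retinoid lists, were chosen after the results were seen; the other lists were fixed before. For the first 3 of these lists, counts are given without the genes whose values were known when they were written. Over all measured genes 3714 were higher and 2735 lower. Of 24 actin, keratin and adhesion genes other than Krt20, 21 were higher, with a median log2 difference of 0.12 at percentile 99.9 of random lists. Itga3, an integrin, stood at 0.49 and Lgals3, galectin-3, at 0.31, and Actn4 was lower at -0.11. Of 15 wound response and YAP target genes other than Thbs1 and Gadd45a, 10 were higher and 5 lower, with a median of 0.17 at percentile 99.8. Fosl1 stood at 0.44 and Ankrd1 at 0.35, and Amotl2 at -0.24. The 12 immediate early and growth factor response genes other than Odc1, Dusp5, Myc and Jun lay within the random range, with a median of 0.06 at percentile 72.0, 7 higher and 5 lower. Lists built after other genes were seen are not independent evidence of a direction.

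Pyruvate carboxylase, an enzyme of gluconeogenesis, was read by its own gene probe set and by 4 control probe sets of the array. The gene Pcx differed by -0.37, and the 4 control probe sets by -0.39, -0.27, -0.33 and -0.69, so all 5 readings were lower with PCN. These readings are of 1 gene in the same RNA and are not independent. The 18S ribosomal RNA control probe sets were lower by as much, at -0.42, -0.67 and -0.34. Those for beta-actin, Gapdh and the transferrin receptor were not, with differences from -0.03 to 0.17. Among the 262 measured unnamed probe sets, none was 2-fold higher and 1 was 2-fold lower, at -1.12.

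The first pattern is that 4 metabolic lists, those of bile acids, glucose handling, fatty acid oxidation and conjugation, were lower together, with a pooled median of -0.21 over 74 genes, among 10 of the 22 lists, cholesterol, acute phase and hepatocyte genes included, that lay below percentile 2.5. A trend with expression level is argued against by each list lying below all 10000 random lists matched on mean expression. The pooled median of -0.24 after the loess trend was removed adds little, since the lists were chosen for lying below matched lists. A lower share of hepatocytes stays open. The 16 measured markers of other cell types had a median of -0.02 with 8 higher and 8 lower, which shows no general rise. Several of them lay close to the floor, so they give little information. The 12 measured P450 genes of families 1 and 2 outside the PXR list were not lower as a group. Their median was 0.05, with 7 higher and 5 lower, but -0.11 without a floor. The 24 measured hepatocyte genes outside these lists had a median of -0.056 (bootstrap interval over genes -0.12 to -0.02). A smaller fall than that of the pattern was likely in advance, because the 4 lists were chosen for lying below all random lists. The 12 of these hepatocyte genes under a log2 level of 12, where the scale may be less compressed, had -0.13 with an interval of -0.44 to -0.03. Both intervals cover the choice of genes on these arrays, not the share of hepatocytes. A difference between the cultures other than PCN, such as cell density or attachment, cannot be told apart from the treatment with 1 array per group.

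The second pattern is that Cyp3a25 was 7.82-fold higher while Cyp3a11 was 1.87-fold higher. If Cyp3a25 probes had read only Cyp3a11 RNA, the Cyp3a25 intensity with PCN would have been at most 271, against 1134 measured. That holds only if the Cyp3a11 fold is not compressed, and Cyp3a11 ranked 65 of the 6449 measured genes by intensity with DMSO, so reading of a relative cannot be told apart from a larger difference of Cyp3a25 itself. Probe sequences were not used here.

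The third pattern is that 4 retinoid genes, Cyp26a1, Dhrs3, Adh1 and Rdh7, were among those lower with PCN. One hypothesis is a general fall of retinoid target genes, which may be seen in other members of a retinoid list. The 12 other measured members, which include Ttr from the hepatocyte list, had a median of -0.013 at percentile 21.8, with 5 higher and 7 lower, from Rarb, the gene of a retinoic acid receptor, at -0.20 to Rarres1 at 0.21 and Rdh10, a retinol dehydrogenase, at 0.40. These 12 went both ways, with a median inside the random range, so no shared fall was seen outside the 4 genes. A weaker remainder was likely in advance, because the 4 were set aside for being lower. The 12 therefore cannot decide on a general fall. The list mixes genes of retinoid metabolism with retinoic acid targets, so a fall limited to the targets stays open. With the 4 genes that prompted it, 11 of 16 measured members were lower, with a median of -0.02 at percentile 14.6; the mean of -0.35 rests on those 4.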
